A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

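The series followed budding yeast (Saccharomyces cerevisiae) lacking or altered in the HMG-box protein Hmo1 and in the DNA topoisomerases Top1 and Top2. RNA sequencing covered 5 libraries, histone H3 chromatin immunoprecipitation (ChIP) 4 libraries, ChIP of Flag-tagged Hmo1 2 libraries, and Top2 chromatin interaction analysis by paired-end tags (ChIA-PET) 1 library. The other 6 of the 18 samples were ChIP inputs, for which no separate values were used here. Each group held 1 library, so no replicate error could be computed and no p-value for a gene or a group is given.

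Per the labels' protocols, RNA was depleted of ribosomal RNA, selected for poly-A tails, and made into strand-specific libraries sequenced on an Ion Proton. Strains were grown at 28 °C and moved to 37 °C for 60 min, except the wild-type 28 °C library, whose label gives arrest in G1 and release for 15 min. Its growth protocol instead describes the move to 37 °C given for all RNA libraries; the sample label was followed. Cells for ChIP spent 2 h and 15 min at 37 °C and were fixed with 1% formaldehyde, for 15 min with shearing to 200 bp for H3 and for 30 min with shearing to 500 bp for Hmo1. The ChIA-PET label says log-phase cells at 28 °C, while its protocol gives G1 arrest and release for 15 min. The TopA plasmid expresses the topoisomerase I of Escherichia coli.

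The authors deposited RSEM expected counts per gene, after alignment with STAR to the R64 build per the submitters' processing notes. The deposited TPM values, made by the authors with RSEM per the file headers, served as an alternative to the counts. Per the submitters' processing notes, the ChIP reads were handled with Picard, SAMtools and deepTools on R64. For H3, the deposited lists give nucleosome positions with a smoothed signal at each summit and a fuzziness score, per the file headers; their column names are those of DANPOS, but the caller is not given in the sources used here. For Hmo1, the deposited lists give a peak score whose scale is not stated, and the peak caller is likewise not given. The ChIA-PET file deposited by the authors gives a count of paired-end tags for each pair of joined anchors, made with cutadapt, BWA, Picard and bedtools per the submitters' processing notes. No build is named for it; anchors shifted in steps of 500 bp met both ends of a gene most often at an offset of 0 bp, so its coordinates were read as R64. No version is given for any of these tools in the sources used here, and no statement on duplicate removal or on thresholds was used.

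Gene names, classes and coordinates came from the reference table of the R64 assembly. Of the 7126 features in the RNA files, 964 had no match in it and keep the identifiers of the files. All 6002 nuclear coding models have lengths that are multiples of 3, so gene starts are start codons and lengths are coding lengths. Strand was taken from the systematic name, and the largest coordinate seen on a chromosome served as its length.

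Expected counts were scaled with TMM factors (edgeR 4.0.16 in R 4.3.3) over the 5 RNA libraries and turned into log2 CPM values with a prior count of 2. Genes with a mean of at least 20 counts over the 5 libraries were kept. A log2 ratio of at least 1, or at most -1, is described as 2-fold higher or lower, a rule of size without a test. The median of each gene list was compared with the medians of 10000 random lists of the same size, drawn within 20 bins of mean expression, and called high or low outside their central 95%. Members of a list are regulated together, so this is a ranking among random lists, not a p-value. The random lists were not matched on coding length. Intervals of single ratios and of percentages are exact (Clopper-Pearson) 95% binomial intervals. For H3 cover, a mean over bases, they take each gene as 1 trial. Intervals of list medians come from order statistics over the members. Where a library had 0 counts, the fold was computed against a floor of 3 counts in that library and is a lower bound. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Departure from additivity was the log2 ratio of the double mutant over wild type minus the sum of the ratios of the single mutants, with 100 Poisson draws as the counting baseline.

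The lists fixed before the data were examined were ribosomal proteins, mitochondrial ribosomal proteins, ribosome biogenesis, RNA polymerase I and III subunits, histones, topoisomerases and HMG-box proteins, condensin and cohesin, heat shock chaperones, general stress response, pheromone response and mating, genes of the G1/S, G2/M and M/G1 phases, DNA damage response, phosphate regulon, galactose regulon, glycolysis, tricarboxylic acid cycle and respiration, amino acid biosynthesis, sulfur assimilation, iron regulon, ergosterol synthesis, proteasome, cell wall integrity, meiosis and sporulation, auxotrophic marker genes, and alpha-cell genes. The script added genes within 20 kb of a chromosome end, the shortest and the longest coding genes, small nucleolar RNAs (snoRNAs) and the mitochondrial genome. Lists needed at least 5 measured members.

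Genes were named by a rule fixed beforehand: HMO1, TOP2 and TOP1 in each RNA comparison; the 8 highest and 8 lowest ratios among nuclear coding genes with a mean of at least 50 counts; up to 3 leading members of each called list; the 10 highest-scoring Hmo1 peaks of each library; the 10 PET clusters with the most tags; and the 5 genes over 1000 bp with the largest gain and the 5 with the largest loss of H3 cover in the topoisomerase mutant. Marker genes outside this rule are named as chosen after their values were seen. Some leading members of called lists are not reported here.

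Regions were analysed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9. A peak or nucleosome was shared when 50% of the shorter region was covered. An Hmo1 promoter peak overlapped the 500 bp before a start codon. Chance levels came from 1000 random placements on the same chromosomes, or 20 for H3. H3 cover was the percent of bases inside called nucleosomes, in 20 bp bins, over the 300 bp before the start codon (promoter), the first 1000 bp of the gene (body, shorter where the gene ended) and the 300 bp after its end (downstream); windows could reach into a neighbouring gene. A PET cluster joined both ends of a gene when its anchors lay within 500 bp of the start and of the end. Intervals of rank correlations with coding length came from 200 bootstrap draws over genes, which are not independent replicates.

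Alternatives planned beforehand were DESeq2 1.42.0 size factors, scaling to the library total, no count filter, a mean of at least 100 counts, a prior count of 0.5, log2(TPM + 1), stricter or looser overlap, the 50% of regions with the highest score or signal, other windows, 150 bp around each nucleosome midpoint, and genes with an isolated start. Coding genes only (planned for the gene lists alone), TMM over the 4 libraries at 37 °C, regions or genes at least 100 kb from a chromosome end, clusters with at least 3 tags, clusters outside the ribosomal DNA, and further peak sets for the bound genes were added after seeing the data. The steps were tested on simulated data. For RNA these were Poisson counts from 1 shared profile of the 37 °C libraries, without variation between cultures. Their rates therefore cover counting error only. In counts simulated on the hmo1Δ to wild-type comparison for 5979 genes, 49 of 49 genes with a 4-fold change and 21 of 50 with a 2-fold change passed the 2-fold rule, as did 9 of 5780 unchanged genes; of 200 simulated lists of 30 genes, 12 were called without a shift and 200 with a shift of 0.5 log2. The overlap rule gave no error in 1200 checks.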

Results

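Hmo1 is an abundant HMG-box protein of budding yeast, and Top1 and Top2 are the enzymes that remove DNA supercoils and links. RNA sequencing compared wild type, hmo1Δ, the temperature-sensitive top2-1 mutant and the hmo1Δ;top2-1 double mutant after 60 min at 37 °C, with a wild-type library from cells in S phase at 28 °C. Nucleosomes called from histone H3 chromatin immunoprecipitation (ChIP) were compared between wild type and top2-1;top1Δ cells, each with a control plasmid or a plasmid for TopA, the topoisomerase I of Escherichia coli. Peaks of Flag-tagged Hmo1 and pairs of DNA segments joined in a Top2 ChIA-PET experiment (chromatin interaction analysis by paired-end tags) completed the set. No replicates were present in any group, so intervals cover counting error only and reads copied by PCR are not independent molecules.

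The 5 RNA libraries held between 4752471 (wild type, 37 °C) and 14770300 (wild type, 28 °C) estimated counts over 7126 features. At 37 °C, nuclear coding genes took 97.9% to 98.1% of the counts, against 77.6% at 28 °C. In the 28 °C library small nucleolar RNAs (snoRNAs) took 5.89%, small nuclear RNAs 2.09%, the RNA of the signal recognition particle 11.2% and the mitochondrial genome 1.02%, whereas snoRNAs took 0.0142% in wild type at 37 °C. Poly-A selection is described for all RNA libraries together, and with this makeup it is uncertain for the 28 °C library, so its ratios cannot be read as RNA levels in the cells alone. The rank correlation of wild type with top2-1 at 37 °C was 0.980, with hmo1Δ 0.912 and with the double mutant 0.941. hmo1Δ and the double mutant correlated at 0.969. Wild type at 28 °C correlated at 0.858 with wild type at 37 °C; the genes behind these values are not independent replicates.

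At 37 °C, cells without Hmo1 had more RNA of genes for the general stress response, histones, sulfur and methionine metabolism and respiration than wild type. They had less RNA of genes for ribosome assembly, RNA polymerases I and III, mitochondrial ribosomes, chromosome cohesion and the G1/S and G2/M phases. Genes for ribosomal proteins as a group lay close to wild type. Of 6085 genes, 434 were at least 2-fold higher and 316 at least 2-fold lower in hmo1Δ, so 57.9% of them were higher. With library totals alone, 32.3% were higher, at an all-gene median of -0.25 log2, and with TPM 27.6%, at -0.31; group directions below hold relative to these medians.

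HMO1 itself (IV: 812110-812850) had 0 counts in hmo1Δ against 1152 in wild type, at least 481-fold lower. RNA of TOP2 (XIV: 457704-461990), the type II topoisomerase, was lower (log2 ratio -0.58, 95% counting interval -0.72 to -0.44), as was TOP1 (XV: 313078-315387), the type I enzyme (-0.51, -0.65 to -0.37). HXT6, a high-affinity glucose transporter nearly identical to HXT7, had the highest ratio, with 936 counts against 0, at least 249-fold higher; its reads cannot be split with certainty between the copies. SPG4, needed for survival in stationary phase, was at 5.37 (4.87 to 6.12), GRE1, a hydrophilin of osmotic stress, at 5.14 (4.76 to 5.64). FMP45, a membrane protein of eisosomes, was at 4.53. RTN2, a reticulon of the endoplasmic reticulum, reached 4.38, DDR2, a stress-induced protein, 4.30, and TKL2, a transketolase, 4.10. Also among the highest was the Ty element frame YMR046C (38.7 counts against 0, at least 10.3-fold). The lowest were HMO1, the marker TRP1 (tryptophan synthesis; 0 counts against 152, at least 63.6-fold lower) and Ty frames, whose copies share reads: YDR261W-B at -4.28, YLR157C-B with 1 count against 38.3 (-4.14, -10.91 to -3.01), YGR038C-B with 0 against 20.7 (at least 8.65-fold lower), YBL100W-B at -3.83, YDR210W-B at -3.78 and YDR034C-D at -3.64.

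Among gene lists, the general stress response stood furthest from wild type, with a median of 2.10 (1.51 to 2.72; random lists -0.15 to 0.25) and 33 of 38 genes at least 2-fold higher. Sulfur assimilation was at 0.70, led by MET6 (methionine synthase, 2.78), SAM2 and SAM1 (S-adenosylmethionine synthetases, 2.61 and 1.95). Histones were at 0.69 (-0.14 to 1.87), with HHF1 (histone H4) at 2.13 and HTA1 and HTA2 (H2A) at 1.87 and 1.25; paralogs share reads. The auxotrophic markers were at 0.64, with ADE2 (adenine synthesis) at 2.54, URA3 (uracil synthesis) at 1.78 and MET17 (homocysteine synthesis) at 1.23. The tricarboxylic acid cycle and respiration were at 0.57 (SDH2, succinate dehydrogenase, 1.23; KGD2, ketoglutarate dehydrogenase, 1.01; COX6, cytochrome oxidase, 0.99). The phosphate regulon was at 0.46 (PHO5, acid phosphatase, 1.37; the transporters PHO84, 1.34, and PHO89, 1.18). Meiosis and sporulation were at 0.42 (DIT1, spore wall, 1.55; DMC1, recombinase, 1.35; MEK1, kinase, 0.95). Genes within 20 kb of a chromosome end were at 0.31, with 30 of 147 at least 2-fold higher, a call lost without a count filter. Their leading members were HSP33 (chaperone-like protein, 135 counts against 1; 5.49, 4.25 to 12.07), MSC1 (mutant with altered recombination, 3.83) and YEL073C (2.60). The M/G1 genes, at 0.26, lay at the edge of the random lists; their call was lost with DESeq2 factors, a prior count of 0.5, coding genes only and TMM over the 4 libraries at 37 °C, and TPM put them at -0.05. PIR3 and PIR1 (cell wall mannoproteins) were at 2.97 and 1.23 and PST1 (cell wall protein) at 2.62.

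The lists lower in hmo1Δ were led by condensin and cohesin at -0.59 (-1.02 to -0.23), with the cohesin subunits MCD1 at -1.58 and SMC3 at -1.32 and the cohesin partner PDS5 at -1.02. Ribosome biogenesis was at -0.56 (-0.62 to -0.51), with LTV1 (small-subunit export) at -1.36, DBP10 (helicase) at -1.28 and RRP12 (pre-ribosome export) at -1.23. RNA polymerase I and III subunits were at -0.49 (RPC19, shared by both enzymes, -1.47; RPC25 -1.04; RPA12 -0.97). G1/S genes were at -0.49 (SVS1, vanadate resistance, -2.40; TOS4, a G1/S regulator, -2.34). G2/M genes were at -0.40 (CHS2, chitin synthase of the septum, -1.44; HOF1, cytokinesis, -1.26; CLB1, mitotic cyclin, -1.19). Mitochondrial ribosomal proteins were at -0.34 (MRP2 -0.93, MRPL13 -0.89, MRP35 -0.79) and ergosterol synthesis at -0.24 (ERG10 -0.93, ERG27 -0.72, ERG3 -0.72). The pheromone response was at -0.32, with BAR1, the protease that degrades alpha-factor, at -2.47 (-2.82 to -2.18), MFA2 (a-factor) at -1.23 and KAR3 (kinesin of nuclear fusion) at -0.79. Ribosomal proteins lay at 0.18 within the range of random lists, and at -0.07 with library totals and -0.19 with TPM. Also within the range were glycolysis (0.48), the galactose regulon (0.34), topoisomerases and HMG-box proteins (-0.16), snoRNAs (0.00) and the mitochondrial genome (0.00). The same held, with a sign that turned under library totals and TPM, for the DNA damage response (0.22), cell wall integrity (0.21), heat shock chaperones (0.20), the iron regulon (0.09), the proteasome (0.07) and amino acid biosynthesis (0.02). The 4 alpha-cell genes had too few members to measure.

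**Figure D1:**
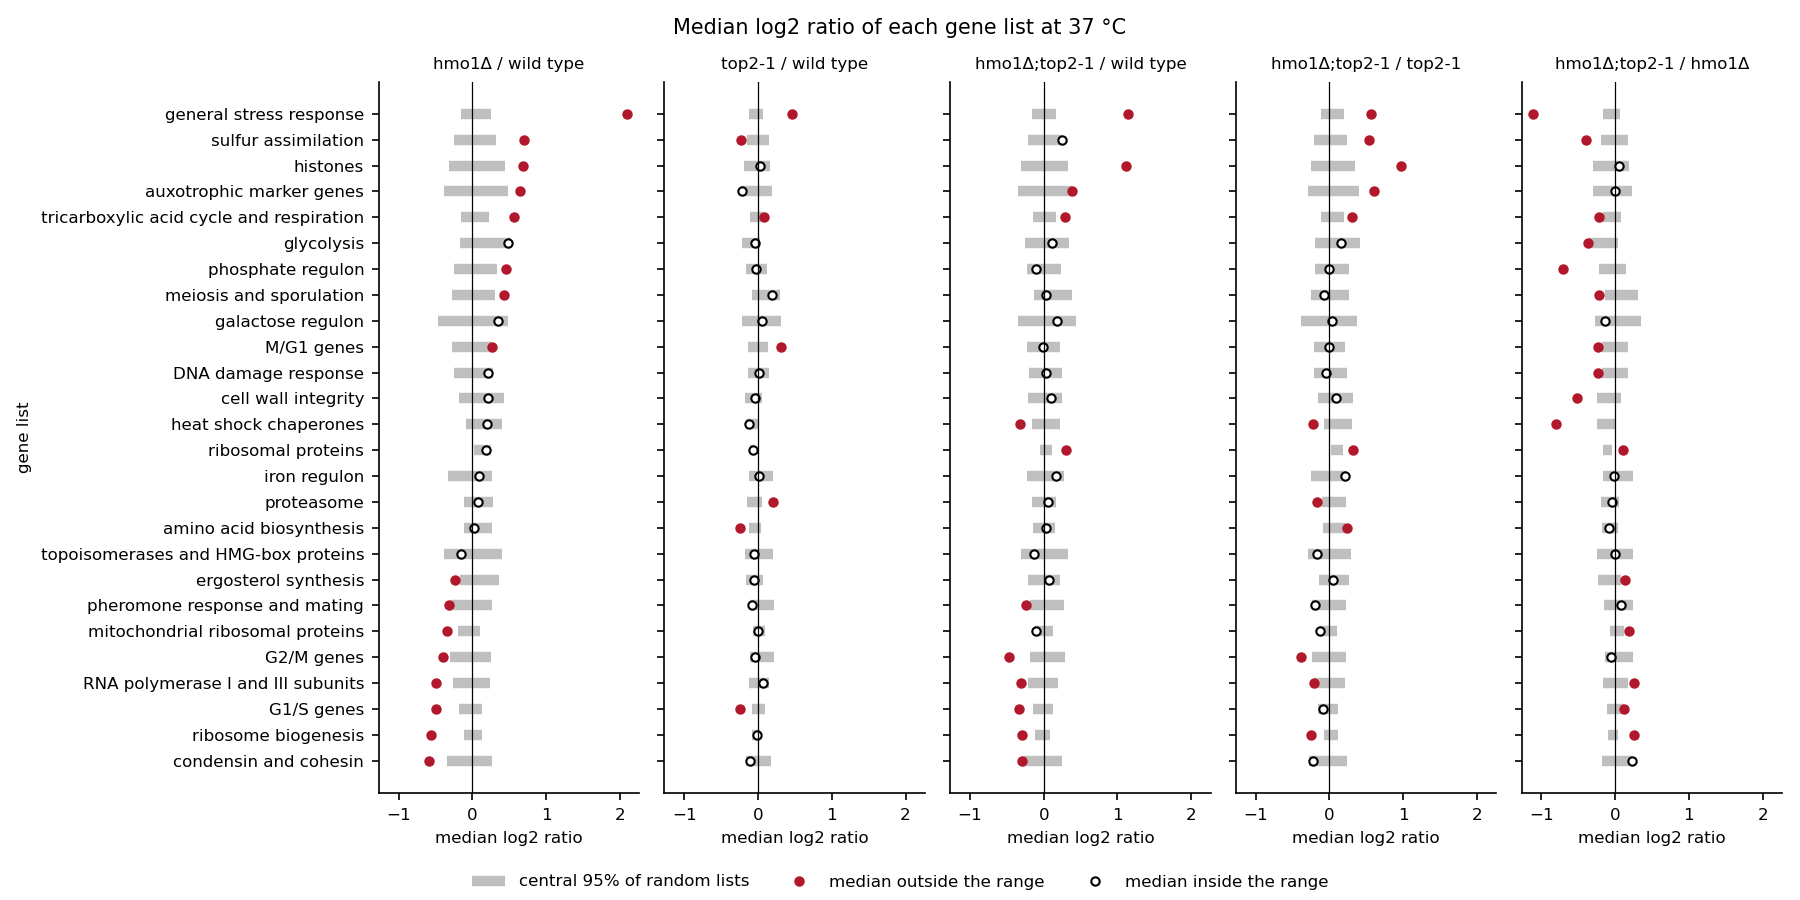
Median log2 ratio of each fixed gene list in 5 comparisons at 37 °C. Bars give the central 95% of random lists of the same size and expression, and filled points lie outside it. The sign of the median for ribosomal proteins, heat shock chaperones, DNA damage, cell wall, iron, proteasome and amino acid genes in hmo1Δ over wild type turns with library totals and TPM, and that for M/G1 genes with TPM. Small medians close to 0 in other panels turn as well.

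Inactivation of Top2 alone left RNA levels near wild type after 60 min. Genes of the stress response, the proteasome and the M/G1 phase were slightly higher, and genes of the G1/S phase, amino acid synthesis and sulfur assimilation slightly lower. Short genes were higher than long ones. Of 6085 genes, 93 were at least 2-fold higher and 52 lower in top2-1 than in wild type (58 and 19 at a mean of at least 100 counts, 186 and 106 without a filter, 40 and 21 with coding genes only). HMO1 lay at -0.06 (-0.18 to 0.05), TOP2 at -0.19 (-0.33 to -0.06) and TOP1 at 0.27 (0.14 to 0.40). The highest ratios were SPG4 (2.59, 2.03 to 3.36), DPI8 (a protein of unknown function, 2.08), DDR2 (1.96), SRX1 (sulfiredoxin of oxidative stress, 1.70). They were joined by Ty or dubious frames with few counts, YLR227W-B (1.73, 0.34 to 4.57), YDR316W-B (8 counts against 1; 1.73, -0.17 to 8.20), YGL088W (at least 1.30-fold higher) and YJR029W (at least 1.19-fold higher). The lowest were the Ty frame YOR192C-A (0 counts against 28.3, at least 11.4-fold lower), CHA1 (serine and threonine catabolism, -1.66), the Ty frame YDR261W-A (-1.62). PCL1 and CLN2 (G1 cyclins) followed at -1.61 and -1.37, with HXT7 (glucose transporter, -1.58), SCW10 (cell wall glucanase, -1.33) and OLE1 (fatty acid desaturase, -1.33).

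In top2-1 the general stress response was at 0.46 (0.29 to 0.71), with DDR2, HOR7 (1.46) and TFS1 (0.96) leading, and snoRNAs were at 0.46, with 20 of 76 at least 2-fold higher at low counts. SNR63 was at least 5.01-fold, SNR18 at least 3.88-fold and SNR72 at least 1.48-fold higher, each from 0 counts in wild type, and with such genes at their bound the median was again 0.46. M/G1 genes were at 0.31 (DSE2 and DSE1, daughter cell separation, 1.08 and 0.76; PIR3 0.82), proteasome genes at 0.20 (PUP2 0.47, RPT2 0.41, PRE9 0.37) and respiration at 0.09 (CIT1, citrate synthase, 0.96; ATP15 0.85; COX7 0.73), the last inside the range with TPM. Lower were G1/S genes (-0.24; PCL1, CLN2 and SVS1, at -1.0, led), amino acid biosynthesis (-0.24; LEU1 -0.69, LYS4 -0.69, ILV3 -0.59) and sulfur assimilation (-0.23; MET6 -0.75, MET32 -0.59, MET16 -0.53). Within the range of random lists were markers (-0.22), meiosis (0.19), heat shock chaperones (-0.12, called low with TPM) and condensin and cohesin (-0.10). The same held for the pheromone response (-0.08), polymerase subunits (0.07), ribosomal proteins (-0.06, called low with TPM), galactose genes (0.06), topoisomerases (-0.05), ergosterol (-0.05), glycolysis (-0.04), cell wall (-0.04), G2/M (-0.04) and phosphate genes (-0.03). DNA damage (0.02), histones (0.02), near-end genes (0.01), iron genes (0.01), ribosome biogenesis (-0.01), mitochondrial ribosomal proteins (-0.01) and the mitochondrial genome (0.00) did not depart from 0 by more than 0.02, and the sign of such values turned between scalings.

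Against wild type, stress genes and histones were higher in the double mutant, as in hmo1Δ, and ribosome biogenesis, polymerase subunits, cohesion, G1/S and G2/M genes were lower. Ribosomal proteins, near wild type in hmo1Δ, were higher. Random lists were not matched on coding length. In this comparison coding genes of a median length of 453 bp were at 0.20 and those of 2877 bp at -0.18. The median of the heat shock chaperones was lower, with members on both sides. Of 6085 genes, 286 were at least 2-fold higher and 217 lower than in wild type (56.9% higher; 48.7% with library totals and 36.0% with TPM, which moved the all-gene median to -0.15). HMO1 (at least 716-fold lower) and TRP1 (at least 94.6-fold lower) had 0 counts, TOP2 was at -0.17 (-0.29 to -0.05) and TOP1 at -0.10 (-0.23 to 0.02). The highest were HXT6 (202 counts against 0, at least 36.1-fold), YMR046C (at least 19.3-fold), SPG4 (3.73) and FMP45 (3.17). HXT7 (3.07) came next, with DDR2 (3.05), SNZ1 (vitamin B6 synthesis, 2.94) and SHM2 (serine hydroxymethyltransferase, 2.81, 2.73 to 2.89). The lowest, after HMO1 and TRP1, were Ty frames that share reads: YLR157C-B (1 count against 38.3; -4.32, -11.49 to -3.58), YGR161W-B (1 against 31; -4.04, -11.20 to -3.27), YPL257W-B (at least 13.7-fold lower), YER138C (at least 12.3-fold lower), YDR261W-B (-3.89) and YDR365W-B (at least 11.2-fold lower).

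Against wild type, the stress response of the double mutant was at 1.14 (0.73 to 1.41; TFS1, a carboxypeptidase inhibitor, 2.75), histones at 1.12 (HHF1 1.95, HTA2 1.27, HTB2 1.25) and ribosomal proteins at 0.30 (RPS29A 1.46, RPS21A 1.38, RPL29 1.35). Respiration was at 0.29 (QCR7 1.07, QCR10 1.06, CIT1 0.95), near-end genes at 0.18 (HSP33 with 61 counts against 1; COS4 2.61; GTT1 2.10) and markers at 0.39 (ADE2 2.66, HIS3 1.05, CAN1 0.43). The snoRNAs were at 0.76 (0.51 with bounds; SNR18 at least 3.40-fold, SNR63 at least 2.86-fold, SNR72 at least 2.15-fold). G2/M genes were at -0.47 (HOF1 -1.64, CLB1 -1.33, CHS2 -1.13), G1/S genes at -0.34 (TOS4 -1.58, SVS1 -1.53, CLN2 -1.21). Heat shock chaperones were at -0.32, with 4 genes at least 2-fold higher and 5 lower (KAR2, the chaperone of the endoplasmic reticulum, -2.09; SSA2 -1.26; BTN2 -1.20) and polymerase subunits at -0.31 (RPC19 -1.0, RPO31 -0.82, RPC25 -0.49). Ribosome biogenesis was at -0.30 (DBP8 -0.88, RRP12 -0.87, RIX1 -0.84), condensin and cohesin at -0.29 (SMC3 -1.12, MCD1 -0.99, SMC2 -0.75) and the pheromone response at -0.24 (BAR1 -1.95, FUS1 -0.81, FIG2 -0.72). The calls for near-end genes without a filter, for markers in 5 settings, for cohesin with TPM and for pheromone genes with TPM or at least 100 counts were lost. Within the range were sulfur (0.25), galactose (0.18), iron (0.16), topoisomerase (-0.14), and mitochondrial ribosomal protein genes (-0.11). So were phosphate (-0.11), glycolysis (0.11, -0.06 with TPM), cell wall (0.09), ergosterol (0.07), proteasome (0.06), DNA damage (0.04, -0.03 with library totals), meiosis (0.03), amino acid (0.02), M/G1 (-0.01) and mitochondrial genome genes (0.00). With TPM the signs for cell wall, ergosterol, proteasome, meiosis and amino acid genes turned as well, and mitochondrial ribosomal proteins were called low.

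The hmo1Δ;top2-1 strain was compared with top2-1 as hmo1Δ was with wild type; both deletion strains also lacked TRP1 counts, so other strain differences are included in both pairs. Stress, histone, sulfur, respiration and ribosomal protein genes were higher in the double mutant than in top2-1, and ribosome biogenesis, polymerase and G2/M genes were lower. The median of the heat shock chaperones was lower, with members on both sides. Of 6085 genes, 229 were at least 2-fold higher and 228 lower (50.1% higher; 39.2% with library totals and 34.2% with TPM, at an all-gene median of -0.12). HMO1 was at least 685-fold lower and TRP1 at least 105-fold lower, TOP2 at 0.03 (-0.09 to 0.15) and TOP1 at -0.37 (-0.48 to -0.26). The highest were HXT6 (202 counts against 1; 5.60, 4.53 to 12.34), YMR046C (at least 23.3-fold), HXT7 (4.64), YOR192C-A (at least 11.9-fold), MET6 (3.13, 3.00 to 3.27), ADE2 (2.76), DAK2 (dihydroxyacetone kinase, 2.76) and RTN2 (2.69). The lowest besides HMO1 and TRP1 were the Ty frames YER138C (at least 24.2-fold lower), YLR157C-B (1 count against 53.6; -4.56, -11.72 to -3.85), YPR158W-B (at least 15.7-fold), YPL257W-B (at least 15.2-fold), YGR161W-B (1 against 37.6; -4.07, -11.22 to -3.31) and YDR261W-B (-3.91).

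In this pair histones were at 0.97 (HHF1 1.49, HTB2 1.49, HTA1 1.15), markers at 0.60, the stress response at 0.56 (RTN2, FMP45 2.45, TFS1 1.79). Sulfur assimilation was at 0.53 (MET6, SAM2 1.76, SAM1 1.68), ribosomal proteins at 0.32 (RPS21A 1.37, RPS28B 1.25, RPS23B 1.18) and respiration at 0.30 (QCR10 1.07, QCR9 0.92, COX6 0.81). Amino acid biosynthesis was at 0.24 (HIS3 1.52, LYS1 1.27, ILV5 1.04) and near-end genes at 0.23 (HSP33 2.24, COS4 2.17, GTT1 1.76), the latter at 0.00 without a count filter. Lower were G2/M genes (-0.39; CLB1 -1.45, HOF1 -1.45, CHS2 -0.98), ribosome biogenesis (-0.25; DBP2, a helicase, -1.62; RRP12 -0.89; DBP8 -0.88). Heat shock chaperones had a lower median, with 3 genes at least 2-fold higher and 2 lower (-0.22, -0.60 to 0.09; KAR2 -1.78, HSP78 -1.06, SSA2 -0.85). The polymerase list was at -0.21 (RPC19 -0.90, RPC25 -0.80), with RRN11, an initiation factor of polymerase I and not a subunit, at -0.79. The proteasome was at -0.17 (PUP3 -0.49, RPN6 -0.42, RPN1 -0.40). Lists within the range were condensin and cohesin (-0.22), iron (0.22), pheromone (-0.19), snoRNAs (0.17), topoisomerases (-0.17), glycolysis (0.16), mitochondrial ribosomal proteins (-0.13), G1/S (-0.09), cell wall (0.09), meiosis (-0.08), ergosterol (0.05), DNA damage (-0.05), galactose (0.04), phosphate (0.00) and M/G1 genes (0.00). The signs for cell wall, ergosterol and galactose genes turned with library totals and TPM, that for snoRNAs with TPM, and that for meiosis genes at a mean of at least 100 counts. TPM called the iron genes high and the mitochondrial ribosomal proteins low.

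In cells without Hmo1, inactive Top2 went with lower stress, chaperone, phosphate, cell wall and sulfur genes. Genes for ribosomes of the cytoplasm and mitochondria and for ribosome assembly were slightly higher. Coding genes of a median length of 453 bp were at 0.14 here, and random lists were not matched on length. Stress and ribosome biogenesis genes stood closer to wild type in the double mutant (1.14 and -0.30) than in hmo1Δ (2.10 and -0.56), whereas ribosomal proteins and heat shock chaperones did not. Of 6085 genes, 105 were at least 2-fold higher and 151 lower than in hmo1Δ (41.0% higher); with library totals, at an all-gene median of 0.19, 66.4% were higher, with TPM, at 0.14, 59.8%, and with a mean of at least 100 counts 32.0%. TOP2 was at 0.41 (0.28 to 0.54) and TOP1 at 0.40 (0.28 to 0.53), while HMO1 had no counts on either side. The lowest were GRE1 (-2.81, -2.97 to -2.67), YDL199C (a putative transporter, -2.80), HXT6 (-2.77), TKL2 (-2.61), BUD25 (bud site selection, -2.58), INO1 (inositol synthesis, -2.35), FMP16 (mitochondrial stress protein, -2.22) and YNL195C (-1.99). The highest were YDR210C-C (8.2 counts against 0, at least 1.85-fold), AAH1 (adenine deaminase, 1.78), YMR045C (Ty frame, 1.73), YER145C-A (1.72), PCC1 (transcription and tRNA modification, 1.41), IZH4 (zinc metabolism, 1.4), YDL085C-A (1.36) and GOT1 (Golgi transport, 1.33).

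By list, the stress response was at -1.11 (-1.30 to -0.73; GRE1, ALD3 -1.98, GND2 -1.91), heat shock chaperones at -0.80 (HSP26 -1.35, HSP78 -1.32, SSA1 -1.28), phosphate genes at -0.71 (PHO5 -1.92, PHO89 -1.67, GIT1 -1.24). Cell wall integrity was at -0.52 (PIR3 -1.32, SPI1 -1.11, HSP150 -0.79), sulfur assimilation at -0.39 (SAM2 -1.16, MET3 -1.0, MET17 -0.88) and glycolysis at -0.37 (TDH1 -0.91, PDC5 -0.87, ENO1 -0.57; call lost at a mean of at least 100 counts). M/G1 (-0.23; CTS1 -0.73, PST1 -0.71), DNA damage (-0.23; DDI2 -0.83, HUG1 -0.72), respiration (-0.22; COX4 -0.83, LSC1 -0.78, KGD2 -0.76), meiosis (-0.21; DIT1 -0.94, REC104 -0.75, SPS100 -0.66) and near-end genes (-0.06, but 0.12 with library totals and 0.08 with TPM; MSC1 -1.86, HSP33 -1.68) were lower too. Higher were snoRNAs (0.76, or 0.47 with bounds; SNR61 and SNR67 with 9 counts each against 0, at least 2.02-fold; SNR85 with 14 against 1), ribosome biogenesis (0.25; EBP2 0.82, SSF1 0.81, RLP7 0.81). So were polymerase subunits (0.25; RPC11 1.0, RPC31 0.80, RPA12 0.66), mitochondrial ribosomal proteins (0.19; MRPL37 0.88, MRP2 0.78, MRP35 0.77), ergosterol (0.13; ERG3 0.64, MVD1 0.38, ERG1 0.36), G1/S genes (0.12; SVS1 0.87, ASF1 0.78, TOS4 0.76) and ribosomal proteins (0.11; RPS29A 1.29, RPS22B 0.93, RPL29 0.92). Within the range were condensin and cohesin (0.22), galactose (-0.14), amino acid (-0.09), pheromone (0.08), histone (0.06), G2/M (-0.06), proteasome (-0.05), iron (-0.02), topoisomerase (0.00), marker (0.00) and mitochondrial genome genes (0.00). Library totals and TPM turned the signs for galactose, amino acid, G2/M, proteasome and iron genes.

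Taking the single mutants as a baseline, 269 of 6085 genes lay at least 2-fold below the sum of the separate log2 ratios in the double mutant and 153 at least 2-fold above it. Counting error alone gave means of 22.8 and 30.0 genes over 100 draws, with maxima of 32 and 43. The excess below the sum turned round with library totals (195 below, 218 above) and with TPM (178 below, 214 above). The ratios of hmo1Δ over wild type and of the double mutant over top2-1, which share no library but include any strain difference common to both deletion strains, correlated across genes at 0.62, and 128 of the 434 and 229 genes 2-fold higher were the same genes (16.3 expected by chance), as were 134 of the genes 2-fold lower (11.8 expected). With TPM the shared higher genes were 80 (5.81 expected) and the shared lower genes 177 (29.3 expected). Library totals gave 94 (8.30 expected) and 186 (27.0 expected). The effect of top2-1 with and without Hmo1 correlated at 0.156, with 17 shared higher genes (1.60 expected) and 3 shared lower genes (1.29 expected). With coding genes only, a setting added after seeing the data, the shared higher genes were 2 (0.314 expected). Genes are not independent replicates in either correlation.

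The wild type at 37 °C differed from S-phase cells at 28 °C in cell cycle stage, temperature and RNA classes present. Genes of S phase, histones, cohesion, amino acid and sulfur metabolism were lower at 37 °C relative to the other genes. Chaperone, mitochondrial ribosome and M/G1 genes were higher. Of 6085 genes, 884 were at least 2-fold higher and 1086 lower (44.9% higher); 87.0% were higher with library totals, where the all-gene median was 0.88, and 95.8% with TPM, where it was 1.90. Negative values below are lower than the other genes in every scaling, but the sign turned with TPM for all coding-gene lists called low, and with library totals too for ribosome biogenesis, phosphate, iron and respiration genes.

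HMO1 was at 0.46 (0.35 to 0.58), TOP2 at -1.65 (-1.75 to -1.55; 0.31 with TPM) and TOP1 at 0.01. The highest ratios were YET2 (endoplasmic reticulum protein, 3.87), CMI8 (3.72), HSP30 (heat shock regulator of the proton pump, 3.63), RGI1 (respiratory growth, 3.61), GPM2 (phosphoglycerate mutase homolog, 3.58), YBL029C-A (3.48), TMA10 (ribosome-associated protein, 3.46) and YPR099C (3.36). The lowest were all Ty frames, whose copies share reads: YMR046C (0 counts against 2425, at least 488-fold lower), YBR012W-A (at least 368-fold), YLR256W-A (2 counts against 4258; -9.55, -13.37 to -8.47), YBL005W-A (at least 325-fold), YPR158W-A (at least 219-fold), YAR010C (at least 191-fold), YMR051C (at least 184-fold) and YML040W (at least 181-fold). All 76 snoRNAs were lower, with a median of -8.47 (-8.31 with bounds; SNR18 0 against 18077 counts, at least 3634-fold; SNR73 at least 2857-fold; SNR40 2 against 23460 counts), and so were all 31 mitochondrial features (-7.69, or -6.67 with bounds; AI2 6 against 30895 counts; COB 3 against 10100).

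Histones were at -2.13 (HTA2 -2.68, HHF1 -2.67, HTB1 -2.50), G1/S genes at -1.53 (RNR1, ribonucleotide reductase, -4.24; PCL1 -3.98; CLN1 -3.34). Condensin and cohesin were at -1.52 (IRR1 -2.48, SMC3 -2.08, SMC1 -1.92), amino acid biosynthesis at -1.32 (ILV5 -3.31, ILV3 -3.25) and sulfur assimilation at -1.22 (MET6 -4.99, MET10 -3.78, MET5 -3.61). Ribosome biogenesis was at -0.84 (REA1 -2.77, RRP5 -2.37, DBP2 -2.31), phosphate genes at -0.80 (PHO5 -2.20, PHO84 -2.08, PHO89 -1.98), iron genes at -0.80 (FET3 -2.91, ISU2 -1.80, SIT1 -1.55) and respiration at -0.65 (ATP2 -1.84, ATP1 -1.73, KGD1 -1.65). Higher were mitochondrial ribosomal proteins (0.89; MRP35 1.88, MRPS8 1.88, MRP17 1.83), M/G1 genes (0.88; PCL9 2.22, PIR1 2.21, DSE3 2.20). So were heat shock chaperones (0.76; HSP30, HSP42 2.19, OPI10 1.97), the proteasome (0.41; RPN12 1.16, RPN8 1.12, RPN9 0.92) and the stress response (0.38; GRE3 2.83, HXK1 2.45, PNC1 2.24; call lost with TPM). Within the range were cell wall (-0.79), glycolysis (-0.69), ribosomal protein (-0.65), marker (-0.65), meiosis (0.57), galactose (-0.52), ergosterol (-0.50), polymerase (-0.42), pheromone (0.31), DNA damage (-0.21), topoisomerase (0.11), near-end (-0.09) and G2/M genes (0.01). Library totals and TPM made all the negative medians among them positive.

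Short coding genes stood above long ones in every comparison. Random gene lists were matched on expression and not on length, so list medians of similar size cannot be told apart from this trend. The rank correlation of the log2 ratio with coding length over 5599 genes was -0.283 (-0.311 to -0.257) for top2-1 over wild type, and genes of a median length of 453 bp were at 0.15 against -0.09 for those of 2877 bp. It was -0.287 for the double mutant over wild type, -0.186 for the double mutant over hmo1Δ, -0.115 for the double mutant over top2-1, -0.113 (-0.136 to -0.0903) for hmo1Δ over wild type and -0.314 for wild type at 37 °C over 28 °C. The shortest genes as a list were called high and the longest low in all 6 comparisons, at 0.12 and -0.08 in top2-1, 0.18 and -0.11 in the double mutant over wild type, 0.06 and -0.04 over top2-1, 0.12 and -0.06 over hmo1Δ, 0.04 and -0.08 in hmo1Δ over wild type, and 0.30 and -0.36 at 37 °C over 28 °C. The sign of the shortest genes turned with library totals and TPM in hmo1Δ over wild type and in the double mutant over top2-1, where TPM put them below random lists, and with TPM alone in the double mutant over wild type. That of the longest genes turned with both in the double mutant over hmo1Δ and at 37 °C over 28 °C. The call of the longest genes in the double mutant over top2-1 was lost with TPM, and that of the shortest in hmo1Δ over wild type without a filter.

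Hmo1 peaks lay often at promoters of ribosomal protein, glycolytic and stress genes in both libraries. In the strain with TopA, which by its label also carries top2-1 and top1Δ, fewer peaks were centred on promoters and more on gene bodies. Genes near chromosome ends and of ribosome biogenesis had few Hmo1 peaks in either library. The control list held 1511 peaks, with a median width of 1319 bp, covering 32.1% of the genome, and the TopA list 1933 peaks covering 34.6%. Of the control peaks 73.5% (71.2 to 75.7) were shared with the TopA list, against 48.1% by chance, and 64% (61.8 to 66.1) of the TopA peaks were shared with the control list, against 41.9%. Midpoints fell in the 500 bp before a start codon for 30.5% (28.2 to 32.9) of the control peaks, above every one of the random placements (mean 21.4%, highest 24.6%), and for 20.7% (18.9 to 22.6) of the TopA peaks, near chance. Gene bodies held 58.4% and 69.4%. Peak scores were lower in the TopA list (median 1.17, highest 1.78) than in the control list (1.35 and 2.82). The shift of midpoints was not separated from this difference in score. The title of the control sample names the topoisomerase mutations as well while its genotype names only the tag, so the strains behind the 2 lists are uncertain. The header line inside the TopA file names the control while its peak names say TopA; the peak names were followed.

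A promoter peak was present at 45.2% of the 6002 genes in the control list and at 41.4% in the TopA list. Ribosomal protein genes had one at 112 of 138 promoters (81.2%, 73.6 to 87.3) and 109 of 138 (79.0%), histones at 10 of 11 and 9 of 11, glycolytic genes at 15 of 17 and 14 of 17, stress genes at 28 of 38 and 29 of 38, and cell wall genes at 16 of 21 and 13 of 21. Heat shock chaperones had a peak at 24 of 34 promoters (70.6%, 52.5 to 84.9) with the control plasmid and at 14 of 34 (41.2%, 24.6 to 59.3) with TopA. Galactose genes had one at 7 of 8 and 8 of 8 and topoisomerase and HMG-box genes at 8 of 10 and 7 of 10. Few peaks met ribosome biogenesis (29.2% and 31.2%), meiosis (24.1% and 20.7%), condensin and cohesin (2 of 14 and 1 of 14) and genes within 20 kb of a chromosome end (25% and 14.9%). Mitochondrial ribosomal proteins (31.3%) and the pheromone response (21.4%) were below random lists in the control list and within them in the TopA list (38.8% and 39.3%), a difference that was not tested. Calls were lost with a window of 1000 bp for condensin and cohesin (6 of 14 in both lists) and for meiosis in the control list (12 of 29). For the 50% of peaks with the highest score they were lost for condensin and cohesin in both lists and for meiosis (4 of 29) and histones (6 of 11) in the TopA list. Galactose genes lost theirs in both lists (5 of 8) and, in the control list, with 1000 bp. Topoisomerase and HMG-box genes were above random lists in the control list at 500 and 250 bp but not with 1000 bp or the highest scores, and in the TopA list at 500 bp they and the cell wall genes lay within them.

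The control peak with the highest score (2.82) lay at RPS4B (VIII: 505117-506117), a ribosomal protein gene. It was followed by peaks at RPS23A (VII: 726516-727306, 2.74), MGA1 and SOL4 (VII: 986467-987798, 2.62; filamentous growth and the pentose phosphate pathway), UTP22 (VII: 661694-662559, 2.55; rRNA processing). The others lay at RPL42B (VIII: 382111-383214, 2.53), RPL25 (XV: 79803-80941, 2.5), AAC1, FET3 and BUB2 (XIII: 386702-389629, 2.49), PDR5 (drug export, XV: 618480-620090, 2.49), PNS1 (XV: 638265-639398, 2.48) and GPH1 (glycogen phosphorylase, XVI: 860260-861521, 2.47). In the TopA list the highest were DIP5 (amino acid permease, XVI: 40260-40816, 1.78), RPS19B and RPL18B (XIV: 62155-63728, 1.73), RPS23A (VII: 726533-727235, 1.70), and RPS8A (II: 88869-89858, 1.64). They were followed by HXK1 (hexokinase, VI: 255342-255774, 1.62), RPL12A (V: 52760-54173, 1.60), RPL32 and ROX3 (II: 44492-46309, 1.57), MGA1 (VII: 986920-987679, 1.57), RPS4B (VIII: 504570-506105, 1.57) and RPL17A (XI: 108876-109609, 1.56).

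**Figure D2:**
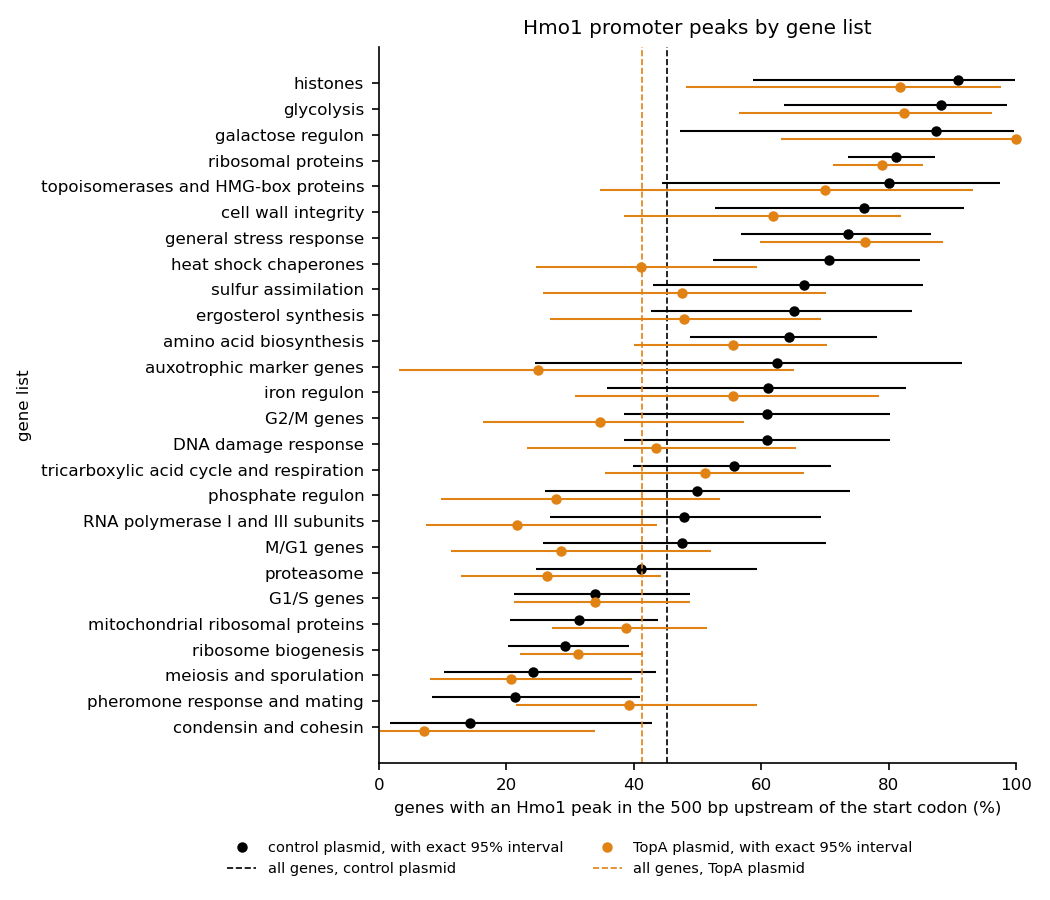
Share of the genes of each list with an Hmo1 peak in the 500 bp before the start codon, for the control plasmid and the TopA plasmid.

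Genes with an Hmo1 promoter peak in the control list stood slightly above random genes when HMO1 was deleted. Their median in hmo1Δ over wild type was 0.06 (0.04 to 0.09; random lists -0.01 to 0.02; 2529 genes), and 241 of them were at least 2-fold higher against 118 lower (163 and 230 with library totals, and with TPM 248 lower against fewer higher); scaling to totals or TPM put the median below 0 but above that of all genes. In the double mutant over top2-1 it was 0.05 (113 higher, 88 lower; 90 and 107 with library totals, 74 and 105 with TPM). Genes with a Top2 ChIA-PET anchor had a median of -0.01 in top2-1 over wild type (2482 genes, 14 higher and 9 lower), just below random lists and slightly above 0 with library totals, and genes joined end to end -0.01 (588 genes, 7 higher and 2 lower), within them.

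Called H3 nucleosomes were rare in gene promoters and followed gene starts in wild type. The list of wild type with control plasmid covered 25.9% of the genome, so a base without a call need not lack a nucleosome. In top2-1;top1Δ cells promoters and gene bodies were both covered more often. Among gene lists, cover of bodies differed widely, without a test of the lists. With TopA in the mutant, nucleosomes were called more densely near the chromosome ends, and their density differed between chromosomes. The lists held 22079 nucleosomes in wild type with control plasmid, 21862 in the mutant with control plasmid, 25035 in wild type with TopA and 10841 in the mutant with TopA. The promoter cover was 2.45% (2.07 to 2.87) in wild type and 5.80% (5.22 to 6.42) in the mutant with control plasmid, and 3.61% and 3.40% in the strains with TopA. These intervals take each of the 6002 genes as 1 trial and do not cover variation between libraries. The first 1000 bp of genes were covered at 31.1%, 35.1%, 37.6% and 15.9% in the order wild type control, mutant control, wild type TopA, mutant TopA, and the 300 bp after genes at 5.47%, 5.39%, 5.52% and 3.53%. Promoter over body was 0.0789 in wild type and 0.165 in the mutant with control plasmid, but 0.0807 and 0.0900 for the 50% of nucleosomes with the highest signal. In the 300 bp on either side of the start codon, wild-type cover was lowest, 1.60%, at 130 bp before it and highest, 30.1%, at 210 bp after it. In the mutant with control plasmid the values were 4.03% at 170 bp before and 41.5% at 210 bp after, and nearer to 1000 bp wild type lay above the mutant.

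**Figure D3:**
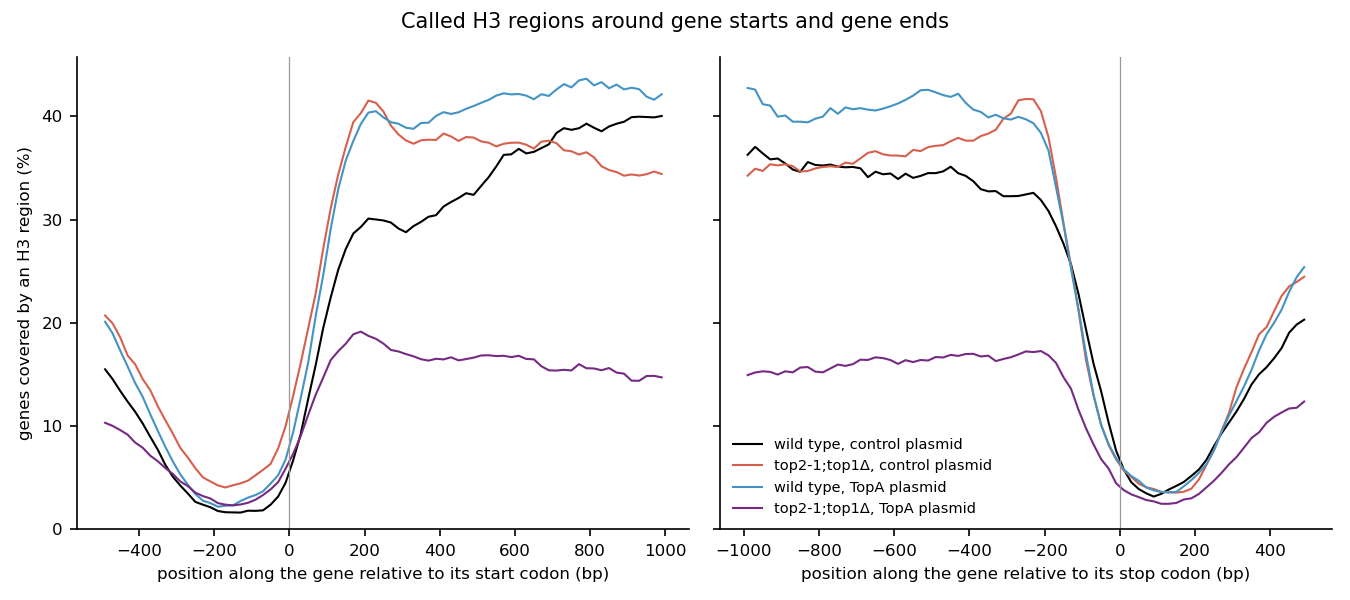
Percent of genes covered by a called H3 nucleosome along gene starts and gene ends, in the 4 libraries.

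Of the wild-type nucleosomes with control plasmid, 47.1% (46.4 to 47.7) were shared with the mutant with control plasmid (25.7% by chance) and 55.0% with wild type with TopA (29.4% by chance). Of the nucleosomes of the mutant with TopA, 52.6% were shared with the mutant with control plasmid (26.0% by chance). Bodies of ribosomal protein genes were covered at 12.4% in wild type and 28.6% in the mutant with control plasmid, glycolytic genes at 14.0% and 47.1%, stress genes at 37.3% and 56.3%, amino acid genes at 36.9% and 50.7% and histone genes at 22.3% and 27.9%. Cover was lower in the mutant for ribosome biogenesis (32.8% and 29.4%), G2/M (40.2% and 32.9%), phosphate (39.3% and 32.2%) and condensin and cohesin genes (25.7% and 21.0%). Wild type with TopA had more cover than with the control plasmid over all genes, and so on ribosomal protein (19.9%), glycolytic (28.0%), stress (48.8%) and G2/M genes (44.6%). The largest gains in the mutant belonged to MRP4 (mitochondrial ribosomal protein, VIII: 99219-100403; 12.5% to 92.7%), ARI1 (aldehyde reductase, VII: 209006-210049; 0% to 76.2%), CTS1 (endochitinase, XII: 708448-710136; 0% to 71.8%), COS6 (subtelomeric protein, VII: 1081584-1082729; 25.8% to 96.2%) and YDL144C (IV: 198662-199732; 13.8% to 81.5%). The largest losses were at STN1 (telomere capping, IV: 610441-611925; 73.4% to 2.29%), AIR1 (RNA surveillance, IX: 210923-212005; 78.7% to 13.7%), SMF3 (iron transport, XII: 210512-211933; 62.9% to 0%), VPS70 (vacuolar sorting, X: 656254-658689; 62.6% to 0%) and LYS9 (lysine synthesis, XIV: 714048-715388; 73.5% to 11.0%).

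Nucleosomes called in the mutant with TopA gathered towards chromosome ends. Of the 10841 nucleosomes, 40.7% lay within 50 kb of an end, a zone with 13.3% of the chromosome length, against 13.9% in wild type with control plasmid, 15.4% in the mutant with control plasmid and 13.8% in wild type with TopA. Their density was 2.78 per kb in the outer 10 kb, 2.48 at 30 to 50 kb, 1.34 at 75 to 100 kb and 0.360 at 400 to 800 kb. The outer 50 kb held at least 2 times the density of the rest on 15 of 16 chromosomes in this list and on 0 of 16 in each of the others. The exception in this list was chromosome VI (1.59 times). Over whole chromosomes, density in this list ranged from 0.502 per kb on XII to 2.71 on VI. On VI the other lists were at 1.94, 2.11 and 2.25. Genes within 20 kb of an end had bodies covered at 57.5% in the mutant with TopA, against 48.3% in the mutant with control plasmid and 38.5% in wild type, whereas amino acid genes had 13.3% and glycolytic genes 9.47% with TopA in the mutant.

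**Figure D4:**
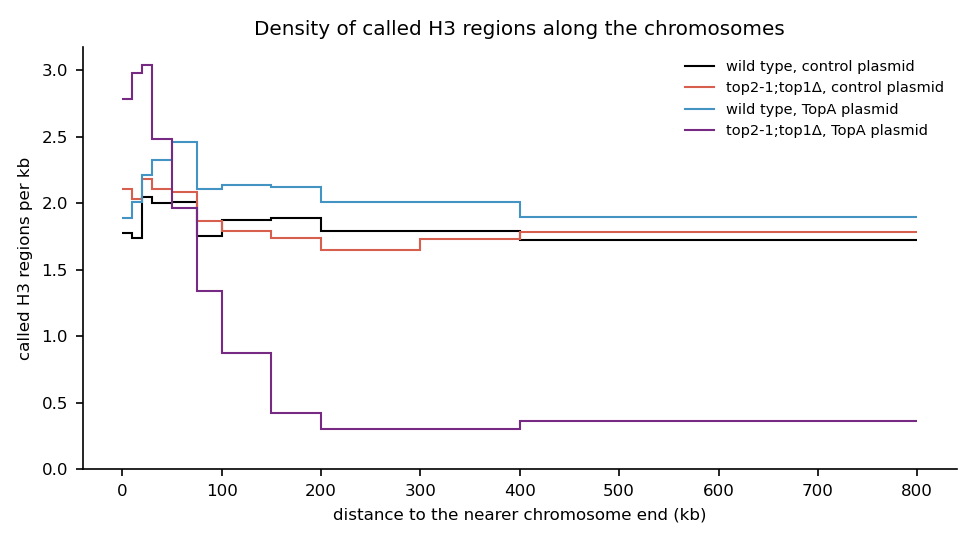
Called H3 nucleosomes per kb by distance to the nearer chromosome end, in the 4 libraries.

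Top2 ChIA-PET clusters joined mostly segments of the same chromosome a short way apart. They joined the start and the end of 1 gene more often than random placements did. The anchors of some clusters overlapped each other. Whether close pairs reflect contact between separate segments or adjoining DNA was not tested. Most clusters between chromosomes touched the ribosomal DNA, a repeat whose copies share reads. Relative to random lists not matched on gene length, more condensin and cohesin genes had an anchor, and fewer ribosomal protein, glycolytic and near-end genes. Of 1887 clusters, 1505 (79.8%) lay within a chromosome, at a median span of 1449.5 bp, and 91.8% of these spanned less than 5 kb. Among 382 clusters between chromosomes, 301 (78.8%) touched the ribosomal DNA (XII: 451575-468931). The effect of its copy number on this share was not tested. Clusters with only 2 tags made up 79.4%. Both ends of a gene were joined by 595 of the clusters within a chromosome (39.5%, 37.1 to 42.1), above all random placements (mean 30.7%, highest 34.1%). Anchors met gene starts in 50.8% of cases, below the chance mean of 55.0%, and gene ends in 51.5%, near the 52.2% of chance. Without clusters that touch the ribosomal DNA, starts were met in 55.5%, equal to the chance mean, and ends in 56.6%, above all placements (mean 52.7%, highest 55.2%).

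An anchor was present at 42.9% of all genes, at 11 of 14 condensin and cohesin genes (78.6%, 49.2 to 95.3), at 43 of 138 ribosomal protein genes (31.2%, 23.6 to 39.6), at 3 of 17 glycolytic genes (17.6%, 3.8 to 43.4) and at 21.0% of genes near chromosome ends. Joins of both gene ends lay below random lists for genes of respiration (0 of 43), mitochondrial ribosomal proteins (2.99%) and genes near ends (4.44%), against 9.9% of all genes. Condensin and cohesin (0 of 14), glycolytic (0 of 17) and topoisomerase and HMG-box genes (0 of 10) had none either, within the range of random lists. An anchor counted anywhere in a gene or in the 500 bp before it, so long genes had more room for one. Joins of both ends depend on gene length as well. The random lists were not matched on length, so the differences between lists cannot be told apart from length. Outside the ribosomal DNA, 40.3% of anchors overlapped a control Hmo1 peak, where chance gave 37.5% and at most 40.2%, and 44.9% a TopA peak, where chance gave 41.6% and at most 44.3%. The cluster with most tags (25) joined URA3 (V: 115944-117074) to VII: 883930-884486. The next joined ESF1 (rRNA processing) to MOR1 and KEI1 (IV: 1205206-1206704 and 1212622-1213650, 12 tags), segments of INP51 (phosphoinositide phosphatase, IX: 350946-352731 and 352360-354751, 11 tags), the 5S gene RDN5-1 (XII: 459726-460064) to XIV: 359341-359388 (9 tags). Further clusters joined segments at IME4, HOS2 and RME2 (meiotic regulation and a histone deacetylase, VII: 141277-143171 and 143288-144596, 8 tags) and XII: 592307-593144 to 599063-599831 (8 tags). Clusters with 7 tags lay at MGP12, INM2 and NSE3 (IV: 1035543-1037193), PAN1 (endocytosis, IX) and OSW2 and SPT8 (XII: 250800-252279), and 1 with 6 tags at FAA3 (fatty acid activation, IX: 339035-340353).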

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

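The tests of the wild-type library, of the scaling and of the strain background for the stress genes, of an even loss and of TopA for the H3 nucleosomes, and of effective length and short-RNA recovery for the length trend were chosen after the result was seen. Every value in this part rests on 1 library per group, and none of the differences between effects was itself tested.

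Several gene lists lay on opposite sides of 0 in the comparisons of top2-1 with and without HMO1, which is why they are listed here. General stress genes were higher with top2-1 in HMO1 cells (0.46) and lower in cells without it (-1.11), a difference of -1.57. The same contrast was -0.54 for M/G1 genes (0.31 and -0.23), -0.30 for respiration (0.09 and -0.22) and 0.36 for G1/S genes (-0.24 and 0.12). The TopA plasmid likewise went with opposite differences in the 2 strains of the H3 experiment. In the topoisomerase mutant the TopA library held 0.496 times as many nucleosomes as the control library, against 1.13 times in wild type, promoter cover differed by -2.40 points against 1.16, and gene-body cover by -19.2 points against 6.58.

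Stress genes stood at 2.10 in hmo1Δ over wild type. A low wild-type library as the whole cause would leave the independent pair unmoved, but the median in the double mutant over top2-1 was 0.56. That is smaller than 2.10, and top2-1 over wild type was at 0.46 and the double mutant over hmo1Δ at -1.11. Single libraries may therefore still account for part of the 2.10. Over the settings the lowest median of the list was 1.77, with TPM and not centred on the other genes. The settings lowered the all-gene median to -0.31 at most, so they could hardly have removed a median of 2.10. They address scaling only within that range. Both deletion libraries also lacked TRP1 (152 counts in wild type), so an effect of HMO1 loss and of another strain background cannot be told apart, because both deletion strains carry the difference. A response to the lack of Hmo1 or of a nutrient may therefore lie behind the pattern, and the labels give no measure of growth state.

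In the mutant with TopA, nucleosomes lay towards the chromosome ends. An even loss from depth or weak signal, without rescaling between libraries, would lower all zones. Yet the outer 30 kb held 1.39 times as many nucleosomes as the control library. The caller and its scaling are not given and the inputs were not used, so weak or uneven signal is not excluded. A signal limit would leave other lists with the same shape, but as many of their strongest nucleosomes gave at most 17.2% within 50 kb of an end. Density in this library also differed between chromosomes, from 0.502 per kb on XII to 2.71 on VI, and the cause of that was not tested. The share in the mutant with TopA exceeded the highest of the other lists by 25.2 points. An action of TopA on chromatin in cells lacking both topoisomerases may cause this, and a fault of this single library cannot be told apart from it, because the combination was sequenced once.

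Short genes stood above long ones in top2-1. Against the effective length of short genes as the whole cause stands the correlation with TPM, -0.276, and against expression level a partial correlation of -0.247 given mean expression. For recovery of short RNAs in library preparation, snoRNAs were higher too, by at least 0.46 in each comparison of top2-1, at low counts. They have no poly-A tail, so their level may follow the poly-A selection, and the test cannot decide. The length trend was also present in hmo1Δ over wild type (-0.113), where snoRNAs lay within random lists. It was present at 37 °C over 28 °C (-0.314), where all snoRNAs were lower. A technical source and a need for Top2 in long genes both remain possible and undecided.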

How the results depend on the processing

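The settings with coding genes only (for counts, additivity, length and bound genes), with TMM over the 4 libraries at 37 °C, at least 100 kb from chromosome ends, with at least 3 tags, without ribosomal DNA, and with the further peak sets were tests chosen after seeing the data; the others were planned. No paired analysis was possible because each group held 1 library. Of 344 recomputed main values 252 stayed within their limits and 92 moved. Of 1440 list medians 1390 kept their side of the range of random lists, 23 gained a call, 23 lost it and 4 came to lie on the other side. Of 2776 recomputed ratios of named genes 2531 stayed within 0.5 log2 and 245 moved; none that was at least 2-fold apart reversed relative to the all-gene median. The planned setting of PET counts at or above the median removed nothing, since the median is the lowest count, and is void. The cause was not tested for any value below unless a cause is given.

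Scaling to library totals changed the genes at least 2-fold higher and lower in hmo1Δ over wild type from 434 and 316 to 279 and 585, and TPM to 244 and 640. For the double mutant over hmo1Δ, library totals gave 198 higher and 100 lower, and for wild type at 37 °C over 28 °C 2734 and 408, with 4973 and 216 by TPM. TPM also gave 174 higher in the double mutant over wild type, 145 over top2-1, 178 genes below additivity and 7 lists called low in top2-1. Without a count filter, which adds genes of few counts, 186 were higher and 106 lower in top2-1, 190 higher in the double mutant over hmo1Δ, and 265 above additivity. With a mean of at least 100 counts, which leaves fewer genes, these were 58, 19, 54 and 73, and with coding genes only 40, 21, 44 and 75.

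Ribosomal proteins, within random lists in the report, were called low with TPM at -0.19 in hmo1Δ and -0.11 in top2-1 over wild type. The shortest genes reversed with TPM to -0.29 in hmo1Δ over wild type and -0.11 in the double mutant over top2-1. The correlation with length moved with TPM to -0.0797 in hmo1Δ and -0.227 in the double mutant over wild type, -0.0591 in the double mutant over top2-1, -0.154 over hmo1Δ and -0.416 at 37 °C over 28 °C, where no filter gave -0.284. Genes with an Hmo1 promoter peak had a median in hmo1Δ over wild type of -0.19 with totals, -0.25 with TPM, 0.0366 without a filter and 0.0948 for peaks in both libraries. Genes with a Top2 anchor were at 0.0166 with totals and -0.0484 with TPM.

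Shared Hmo1 peaks of the control and TopA lists were 78.0% and 68.4% with any overlap, 32.6% and 25.5% with 50% of both peaks, and 69.2% and 60.5% for the 50% of peaks with the highest score. The latter put 39.2% and 25.3% of midpoints in promoters. A window of 250 bp gave 16.1% and 11.3%, and one of 1000 bp 51.2% and 41.5%, as its size dictates.

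For H3, nucleosomes of wild type shared with the mutant, both with control plasmid, were 66.3% with any overlap, 32.7% for the 50% with the highest signal and 45.8% at least 100 kb from chromosome ends. In the same order, wild-type nucleosomes shared with wild type with TopA were 77.7%, 38.3% and 54.3%, those of the mutant shared with the mutant with TopA 37.7%, 19.3% and 14.6%, and those of the mutant with TopA shared with the mutant 72.7%, 38.7% and 58%. Promoter cover for the 50% with the highest signal was 1.17%, 1.69%, 1.34% and 1.59% (wild type and mutant with control plasmid, then wild type and mutant with TopA), and body cover 14.5%, 18.7%, 18.7% and 7.83%, as fewer nucleosomes cover less. At least 100 kb from the ends, promoter cover was 1.57%, 4.73%, 2.62% and 1.08%, and body cover 33.1% in the mutant, 36.2% in wild type with TopA and 8.08% in the mutant with TopA. Genes with isolated starts had promoter cover of 4.26% and 4.11% in wild type and mutant with TopA, and body cover of 37.1% in the mutant with control plasmid and 17.6% with TopA.

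PET clusters joining both gene ends were 5.98% with a window of 0 bp, 64.8% with 1000 bp and 54.7% with at least 3 tags. The chance means were 3.64%, 59.8% and 41.6%. Anchors at gene starts were 18.8%, 70.1% and 56.9%, and 55.5% without ribosomal DNA (19.4%, 76.5%, 61.3% and 55.5% by chance). Those at gene ends were 19.8%, 70.6%, 60.9% and 56.6% (18.2%, 74.3%, 58.4% and 52.7% by chance). Depth limits the snoRNAs and the mitochondrial genome at 37 °C, where differences in most single features were not detectable at this depth.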

Other observations

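The tests of the adenine genes and of the ribosomal protein genes were written before their results were seen, the former after ADE2 and SHM2 had been noticed; the other values were chosen after they were seen, without tests. Cells without Hmo1 had more RNA of genes for the synthesis of adenine and of its one-carbon units. ADE2 was at 2.54 in hmo1Δ over wild type and SHM2 at 2.70. The hypothesis was that the pathway as a whole is higher without HMO1, and it was tested on a written list without these 2 genes, 13 of 14 of which were measured. Their median was 0.88 in hmo1Δ over wild type (random lists -0.24 to 0.50), with 6 genes at least 2-fold higher, and 0.72 in the double mutant over top2-1 (random lists -0.21 to 0.36), with 5. The range over the settings was 0.56 to 0.89 and 0.59 to 0.72. GCV2 and GCV1 (glycine cleavage) were at 2.47 and 2.35, ADE17 at 2.20, MTD1 at 1.4 and ADE4 at 1.05, whereas ADE13 was at 0.12. A lower supply of adenine to the deletion strains, or their genotype at ADE2, may contribute, and neither was measured.

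Hmo1 sat at most ribosomal protein promoters, so the genes with a peak were asked whether they stood lower without HMO1. The 112 genes with a peak had a median of 0.05 and the 26 without 0.41 in hmo1Δ over wild type. The difference of -0.36 lay just inside the central 95% of 10000 random splits (-0.37 to 0.39), so a link between the peak and the level cannot be told apart from chance with 26 genes in the smaller group.

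The marker genes differed between strains beyond TRP1. URA3 had 636 counts in wild type at 37 °C, 2747 in hmo1Δ, 690 in top2-1 and 1590 in the double mutant. The 25-tag cluster of URA3 with chromosome VII was the strongest of the ChIA-PET file. MATALPHA1 had 0 counts in all 5 libraries. HXT7 had 258 counts in wild type, 4296 in hmo1Δ, 103 in top2-1 and 4054 in the double mutant.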
